A study of Mus musculus with 26 samples.

How the data were processed

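Total RNA from the inguinal mammary gland of 26 mice was extracted with a Qiagen RNeasy kit, labelled as biotinylated cRNA and hybridised to Affymetrix mouse genome arrays, 1 array per animal, per the labels' protocols. The deposited values are log2 expression values per probe set, made by the authors with RMA (background correction, quantile normalization and a summary over probes), per the submitters' processing notes. The software version and the chip definition were not stated, nor whether all arrays were processed together. The values ran from 2.34 to 15.1 without a missing value, and were used as deposited.

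Of 45101 probe sets, 64 Affymetrix controls were left out of the tests and 45037 were tested. A gene symbol came from an annotation table of the array. It gave 34945 probe sets 1 symbol, 932 several and 9160 none, for 18193 genes. A gene was represented by its probe set with the highest mean over all arrays, and for named genes other probe sets called in the opposite direction are given beside it. Milk genes near the highest value of the table in both groups were not read as a test of a difference. Probe sets without a symbol were tested but are not named.

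Groups were pregnancy day 12 CBA/CaH and QSi5 (5 arrays each), lactation day 9 CBA/CaH and QSi5 (3 each) and lactation day 9 AIL, with code AC or AQ (5 each). Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 1 on the 16 parental arrays for stage, strain and their interaction, and 1 on the 16 lactation arrays for AIL. P-values were adjusted by Benjamini-Hochberg over all tested probe sets, and a probe set was called at an adjusted p under 0.05. Fixed lists of genes (29 lists, 435 of 468 members measured) were tested with camera at a preset correlation of 0.01, called at an adjusted p under 0.05 over the lists of a comparison, beside camera with an estimated correlation, with which no list of any comparison was called, and beside fry.

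The position of each AIL array between the parental lactation arrays was the projection on the line between the parental means over the probe sets called for strain at pregnancy. AQ and AC codes were compared with an exact two-sided permutation test. The line is set by the parental lactation arrays themselves, and placement was tested on simulated data, where arrays set at 25% and 75% were found at 26.4% and 73.9%. The simulated AIL arrays had no other difference from the parental arrays. The simulation therefore does not test placement where the sets of arrays differ, as they did in the data. The models were tested on simulated data too, with 72% to 95% of changes of 1 log2 unit recovered in most comparisons, but 54% for strain at lactation and 27% for the interaction. Between 4 and 12 false calls were made.

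Named genes followed a rule. It took the 5 genes with the highest and the 5 with the lowest difference among called genes whose groups did not overlap (without that condition for the interaction and for contrasts with the mean of the parents), up to 4 called and 2 not called members of a described list, and a fixed set of mammary genes whatever their result. Groups, lists, tests, this rule and most alternatives were chosen before the data were examined. Alternatives were a filter on mean level, another variance model, quantile normalization, equal array medians, other sets of arrays in the fit, array weights, other probe set choices, a block on replicate numbers, and each replicate left out in turn. Cyclic loess, the Gapdh covariate and leaving out arrays that stood apart (a Gapdh 3' minus 5' value or a tissue marker median over 1 log2 unit above the array's group) were added later, as was a factor for the 2 sets of AIL arrays. Figures were drawn with matplotlib.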

Results

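Gene expression was measured in the inguinal mammary gland of 26 mice, with 1 array per animal. The inbred strains CBA/CaH and QSi5 were sampled on day 12 of pregnancy (5 arrays per strain) and on day 9 of lactation (3 arrays per strain). Mice of an Advanced Intercross Line of these strains (AIL, generation 14) were sampled on day 9 of lactation and carried the sample code AC (5 arrays) or AQ (5 arrays). The labels do not say what AC and AQ stand for. The array medians lay between 4.9957 and 5.2974 on the log2 scale, and the number of arrays limits the precision of every value. The first principal component of all arrays held 58.7% of the variance and separated the pregnancy arrays from the lactation arrays. The second held 12.8%.

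Marker genes of other tissues differed between arrays of 1 group. The median of the skeletal muscle markers was 4.69 log2 units above the mean of all arrays on the pregnancy QSi5 array 3 and 3.36 above it on the array AIL AC1. Brown adipocyte markers stood 3.57 above it on the pregnancy CBA/CaH array 5, and B and plasma cell markers 1.62 above it on the lactation QSi5 array 2. The 3' minus 5' value of Gapdh was 6.50 on the pregnancy QSi5 array 4, against 1.20 to 1.74 on the other arrays of its group. Pregnant CBA/CaH mice had a mean of 2.09 (SD 0.745, n = 5), with 0.89 on array 4 and 2.00 to 2.86 on the others. Apart from the arrays numbered 4, the value was thus higher in CBA/CaH than in QSi5 without overlap. Strain at pregnancy is therefore nearly confounded with it. The poly-A transcripts added to each sample had a value of 4.61 on the pregnancy QSi5 array 4, against 1.29 to 1.57 on the others of its group. The Gapdh value can therefore not be read as RNA integrity alone. In all, 7 arrays stood apart by such a measure. Leaving them out kept 3 pregnancy CBA/CaH, 2 pregnancy QSi5, 2 lactation QSi5 and 4 AIL AC arrays. A call lost in that setting can come from fewer arrays alone.

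The first question was how the gland changed between mid-pregnancy and established lactation in each strain. Csn1s2b, which encodes a milk casein, rose most of the named genes, by 9.34 log2 units in CBA/CaH (SE 0.46, adjusted p = 2.58e-09, n = 5 and 3) and by 9.44 in QSi5 (SE 0.46, adjusted p = 1.48e-09, n = 5 and 3). Its lactation means of 14.7 lay close to the highest value of the table, so these are lower bounds. Atp2b2, a calcium pump of the secretory cell, rose by 6.07 and 7.02 (SE 0.32 for both), and Ccl28, a chemokine that draws plasma cells, by 5.07 and 5.55 (SE 0.24 for both). Rspo1, a secreted enhancer of Wnt signalling, fell by 6.86 in CBA/CaH and fell by 6.94 in QSi5 (SE 0.29 for both). Mcm5, a subunit of the replicative helicase, fell (-5.76 in CBA/CaH and -5.46 in QSi5, SE 0.27 for both). In each of these genes no pregnancy array overlapped a lactation array of its strain.

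**Figure D1:**
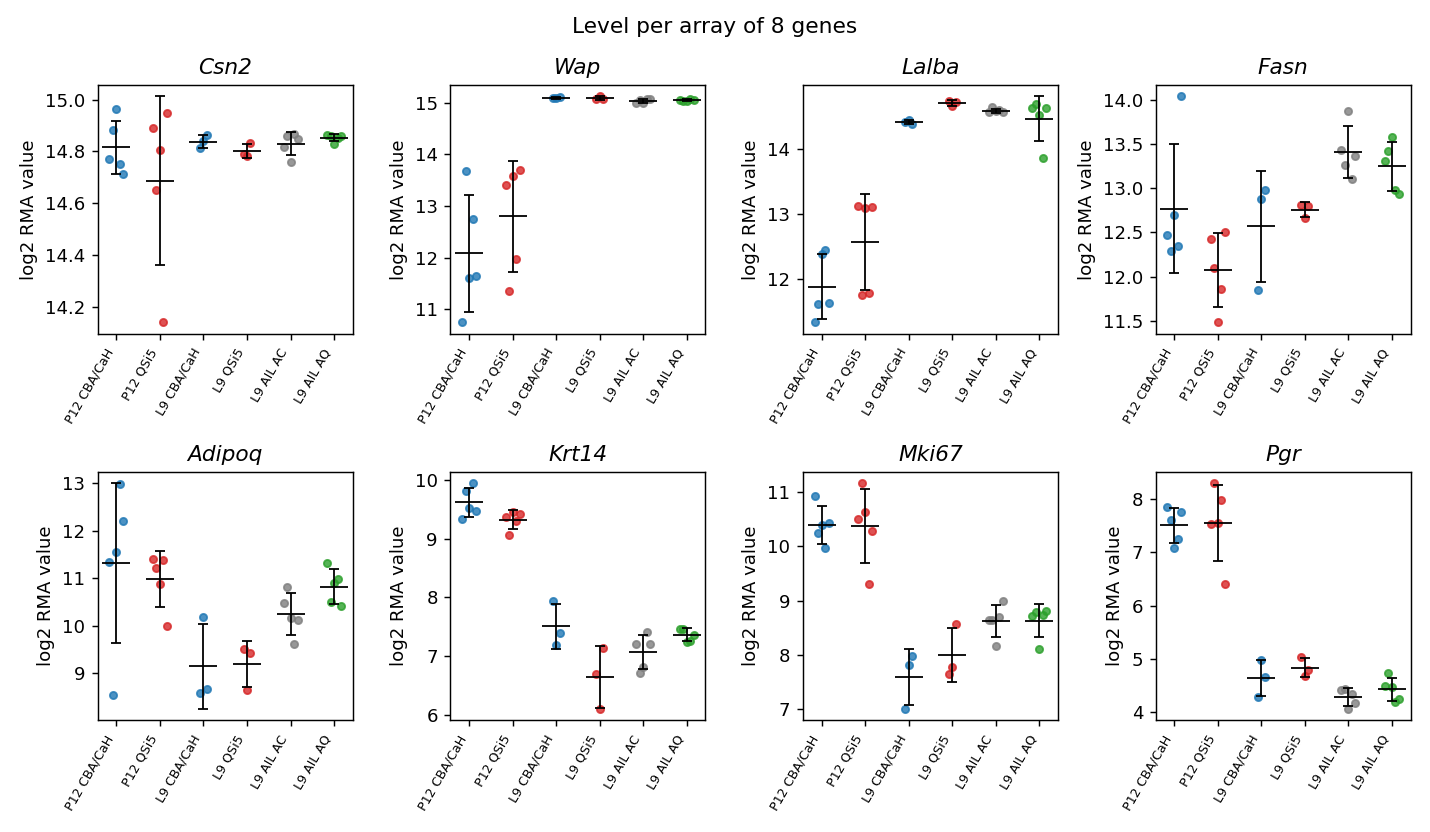
Level of 8 genes on each array (log2 RMA value), by group. Points are arrays, bars are the group mean and SD. Csn2 lay near 14.8 in every group, close to the highest value of the table, while Mki67, Krt14 and Pgr were lower on the lactation arrays of the parental strains than on their pregnancy arrays.

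Genes of milk secretion rose as a group. Of 12 milk protein genes, 8 rose in CBA/CaH and 9 in QSi5 (8 and 9 adjusted over the list alone). The list was called in both strains (camera, adjusted p = 0.000204 and 0.000561), with adjusted p = 0.569 and 0.573 with an estimated correlation. Wap, a whey protein, rose by 3.01 and 2.29 (SE 0.58 for both), Lalba, the lactose synthase regulator, by 2.53 and 2.14 (SE 0.34 for both), and Cel, a milk lipase, by 4.86 and 4.03 (SE 0.56 for both). Wap and Lalba lay near the top of the range at lactation, so their differences are lower bounds. Csn2, which encodes beta-casein, was at 14.8 (SD 0.10, n = 5) in pregnant CBA/CaH mice, near the top of the range at both stages. Its differences (0.02, SE 0.15, adjusted p = 0.911, and 0.11, SE 0.15, adjusted p = 0.533) therefore do not test whether it changed. Of 10 milk fat globule and droplet genes, 7 rose and 2 fell in each strain (the same counts adjusted over the list alone). That list had an adjusted p = 0.0318 and 0.0312, against adjusted p = 0.569 and 0.573 with an estimated correlation. Cidea, a lipid droplet protein, rose by 4.07 and 6.03 (SE 0.68 for both; lactation means of 14.2, also high in the range) and Xdh, a structural partner of the droplet coat, by 2.81 and 2.32 (SE 0.38 for both). Of 19 ion, amino acid and zinc transporters, 10 rose and 3 fell in CBA/CaH, and 11 rose and 3 fell in QSi5 (11 and 3 in each strain adjusted over the list alone). Slc39a8, a metal importer, rose by 4.90 and 4.98 (SE 0.28 for both) and Slc34a2, a phosphate carrier, by 3.75 and 4.78 (SE 0.31 for both). The transporter list was called in both strains (adjusted p = 0.00599 and 0.0202), with adjusted p = 0.569 and 0.573 with an estimated correlation.

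Lipid synthesis genes split. Of 27 fatty acid and triglyceride synthesis genes, 10 rose and 5 fell in CBA/CaH, and 15 rose and 3 fell in QSi5 (10 and 5, and 16 and 3, adjusted over the list alone). The list was called in QSi5 (adjusted p = 0.0193, and adjusted p = 0.645 with an estimated correlation) but not in CBA/CaH (adjusted p = 0.344). Olah, the thioesterase that releases medium-chain fatty acids, rose by 4.06 and 3.87 (SE 0.52 for both), and Elovl5, a fatty acid elongase, by 1.86 and 2.98 (SE 0.28 for both). Srebf1, a transcription factor of lipid synthesis, fell by 1.15 in CBA/CaH and fell by 1.27 in QSi5 (SE 0.34 for both, adjusted p = 0.0107 and 0.00503). After quantile normalization the Srebf1 difference was not called (adjusted p = 0.167 and 0.074), nor after cyclic loess (adjusted p = 0.216 and 0.156), nor was it in CBA/CaH without the lactation CBA/CaH array 1 (adjusted p = 0.0579). Scd1, a desaturase, rose in QSi5 by 0.93 (SE 0.34, adjusted p = 0.030), a call lost with array medians set equal (adjusted p = 0.104), without the arrays that stood apart (adjusted p = 0.214) and without any 1 of the pregnancy QSi5 arrays 3 and 4 or the lactation QSi5 arrays 1, 2 and 3 (adjusted p = 0.0528 to 0.0806). Fasn differed by -0.20 in CBA/CaH (SE 0.36, adjusted p = 0.659) and by 0.69 in QSi5 (SE 0.36, adjusted p = 0.114), and Thrsp by -0.15 and 0.38 (SE 0.25 for both, adjusted p = 0.629 and 0.204). In CBA/CaH, Fasn was 14.0 on the pregnancy array 5 (others 12.3 to 12.7) and 11.8 on the lactation array 1 (others 12.9 and 13.0). The list median was 0.45 on the former (others -0.98 to -0.44) and -0.68 on the latter (others 0.08 and -0.06). Both arrays lower the CBA/CaH difference, so a list call in QSi5 alone does not show that the strains differ. In QSi5, cyclic loess gave calls for Fasn (1.13, adjusted p = 0.0264) and Thrsp (0.81, adjusted p = 0.0206), and Fasn was also called after quantile normalization (0.95, adjusted p = 0.0493) and with only the compared groups in the fit (adjusted p = 0.0323).

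Genes of cell division fell together. Of 29 cell cycle genes, 25 fell and 2 rose in each strain (the same counts adjusted over the list alone). The list was called in CBA/CaH (adjusted p = 1.39e-10) and QSi5 (adjusted p = 4.40e-09), with adjusted p = 0.379 and 0.529 with an estimated correlation. Mki67, a proliferation marker, fell (-2.80 in CBA/CaH and -2.38 in QSi5, SE 0.35 for both), and Mcm7, another helicase subunit, fell (-5.27 in CBA/CaH and -4.78 in QSi5, SE 0.25 for both).

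Markers of luminal and myoepithelial cells also fell. Of 12 luminal markers, 11 fell and 1 rose in each strain (the same counts adjusted over the list alone; adjusted p = 9.65e-05 and 7.39e-05, with adjusted p = 0.379 and 0.529 with an estimated correlation). Kit, a receptor of luminal progenitors, fell by 3.13 in CBA/CaH and fell by 4.49 in QSi5 (SE 0.53 for both), and Pgr, the progesterone receptor, fell (-2.86 in CBA/CaH and -2.71 in QSi5, SE 0.32 for both). Dimmer probe sets of Pgr rose, by up to 0.61 in CBA/CaH and up to 0.68 in QSi5. Esr1, the oestrogen receptor, was the member that rose, by 0.58 in CBA/CaH (SE 0.22, adjusted p = 0.0331) and 1.07 in QSi5 (SE 0.22, adjusted p = 0.000671). The CBA/CaH call of Esr1 was lost with array medians set equal (adjusted p = 0.138), without the arrays that stood apart (adjusted p = 0.0543) and without any 1 of the CBA/CaH pregnancy arrays 1, 2 and 3 or lactation arrays 2 and 3 (adjusted p = 0.0507 to 0.178). Of 11 myoepithelial markers, 7 fell in CBA/CaH and 9 in QSi5 (the same counts adjusted over the list alone; adjusted p = 0.0253 and 0.00187, with adjusted p = 0.569 and 0.573 with an estimated correlation). Krt14, a basal keratin, fell (-2.11 in CBA/CaH and -2.67 in QSi5, SE 0.22 for both), while a second, dimmer probe set of Krt14 rose by 0.88 and 0.81. Trp63, a basal transcription factor, fell (-3.36 in CBA/CaH and -3.31 in QSi5, SE 0.26 for both), while dimmer probe sets of it rose, by up to 0.47 in CBA/CaH and by 0.66 in QSi5.

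Stromal, vascular and fat cell markers fell as well. Of 18 fibroblast and matrix genes, 16 fell in each strain (17 and 16 adjusted over the list alone; adjusted p = 0.000610 and 0.000561, with adjusted p = 0.569 and 0.573 with an estimated correlation). Lum, a matrix proteoglycan, fell (-2.94 in CBA/CaH and -2.57 in QSi5, SE 0.44 for both). Of 11 endothelial markers, 7 fell in each strain (the same counts adjusted over the list alone; adjusted p = 0.0245 and 0.0146, with adjusted p = 0.569 and 0.573 with an estimated correlation), among them Vwf, a clotting factor made by endothelium. The endothelial list was not called without the arrays that stood apart (adjusted p = 0.0571 and 0.0590), with 7 and 5 members lower. Of 13 white adipocyte markers, 11 fell in CBA/CaH and 6 in QSi5 (12 and 5 adjusted over the list alone; adjusted p = 0.00141 and 0.0289, with adjusted p = 0.569 and 0.645 with an estimated correlation), or 7 and 2 without the arrays that stood apart. Adipoq, an adipocyte hormone, fell in CBA/CaH (-2.18, SE 0.72, adjusted p = 0.0186) and in QSi5 (-1.79, SE 0.72, adjusted p = 0.0426). Cyclic loess ended both Adipoq calls (adjusted p = 0.103 and 0.233), as did quantile normalization (adjusted p = 0.0893 and 0.244) and leaving out the arrays that stood apart (adjusted p = 0.0924 and 0.160), the lactation CBA/CaH array 1 or 3 in CBA/CaH (adjusted p = 0.0751 to 0.0765) and any QSi5 array but the pregnancy array 5 in QSi5 (adjusted p = 0.0591 to 0.145). Cidec, a lipid droplet protein of fat cells, fell in CBA/CaH (-3.38, SE 0.76) and in QSi5 (-2.16, SE 0.76, adjusted p = 0.0231), the latter call lost without the lactation QSi5 array 1 or 2 (adjusted p = 0.053 to 0.099) after cyclic loess (adjusted p = 0.0999) and without the arrays that stood apart (adjusted p = 0.125).

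Genes of fatty acid breakdown and respiration fell. Of 15 fatty acid oxidation genes, 14 fell in each strain (the same count adjusted over the list alone; adjusted p = 1.31e-05 and 0.000561, with adjusted p = 0.569 and 0.573 with an estimated correlation). Acadl, an acyl-CoA dehydrogenase, fell (-3.60 in CBA/CaH and -3.73 in QSi5, SE 0.38 for both), and Slc25a20, the mitochondrial carnitine carrier, fell (-3.05 in CBA/CaH and -2.56 in QSi5, SE 0.32 for both). Of 18 mitochondrial respiration genes, 13 fell in CBA/CaH and 11 in QSi5 (the same counts adjusted over the list alone; adjusted p = 0.000886 and 0.0361, with adjusted p = 0.569 and 0.665 with an estimated correlation). Idh3a, of the citric acid cycle, fell (-2.18 in CBA/CaH and -1.86 in QSi5, SE 0.44 for both), while another probe set of Idh3a rose by 0.98 and 1.07. The mean of all its probe sets was not called (-0.46, adjusted p = 0.114, and -0.09, adjusted p = 0.752).

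Immune markers moved in several directions. Of 11 B and plasma cell markers, 5 rose in CBA/CaH and 10 in QSi5 (3 and 11 adjusted over the list alone), and of 14 T and NK cell markers, 5 rose in CBA/CaH and 9 in QSi5 (4 and 10 adjusted over the list alone). Both lists were called in QSi5 (adjusted p = 0.00318 and 0.0122, with adjusted p = 0.573 for both with an estimated correlation) and not in CBA/CaH (adjusted p = 0.085 and 0.344). Jchain, the chain that joins secreted antibodies, rose in QSi5 by 3.60 (SE 0.82, adjusted p = 0.00163) and differed by 1.07 in CBA/CaH (SE 0.82, adjusted p = 0.282). Without the pregnancy CBA/CaH array 4 the CBA/CaH difference was 1.87 and called (adjusted p = 0.00956). Ms4a1, the B cell antigen CD20, rose in QSi5 by 1.63 (SE 0.64, adjusted p = 0.0385). Without the lactation QSi5 array 2 the Ms4a1 difference was 0.37 (adjusted p = 0.377), and without the pregnancy QSi5 array 1, 2 or 5 it stayed between 1.5 and 1.64 but was not called (adjusted p = 0.056 to 0.0685). It was not called after quantile normalization (adjusted p = 0.0924), cyclic loess (adjusted p = 0.134), with equal array medians (adjusted p = 0.0805), with only the compared groups (adjusted p = 0.104), with array weights (adjusted p = 0.056) or with the Gapdh value as a covariate (adjusted p = 0.0517). Cd8a, a T cell coreceptor, rose by 1.14 and 1.36 (SE 0.17 for both). Of 13 MHC and antigen processing genes, 9 fell and 2 rose in each strain (10 and 2, and 9 and 3, adjusted over the list alone). That list was called in CBA/CaH (adjusted p = 0.0318, with adjusted p = 0.569 with an estimated correlation) and not in QSi5 (adjusted p = 0.0954). Of 13 immediate early genes, 7 fell and 1 rose in CBA/CaH, and 10 fell and 1 rose in QSi5 (the same counts adjusted over the list alone; adjusted p = 0.0377 and 0.00327, with adjusted p = 0.569 and 0.573 with an estimated correlation). In CBA/CaH that list was not called without the arrays that stood apart (adjusted p = 0.0550). Egr1 fell (-3.36 in CBA/CaH and -3.52 in QSi5, SE 0.42 for both). The lists of cholesterol synthesis, lactose synthesis and glucose use, prolactin and STAT5 signalling, brown adipocytes, lymph node stroma, macrophages, skeletal muscle, erythroid genes, interferon response, involution and acute phase, endoplasmic reticulum folding, IGF and insulin signalling, and circadian clock were not called in either strain (adjusted p = 0.071 to 0.952 in CBA/CaH and 0.0893 to 0.955 in QSi5). Without the arrays that stood apart, cholesterol synthesis in CBA/CaH, MHC in QSi5, and skeletal muscle and prolactin signalling in both strains passed the threshold. Elf5, a regulator of alveolar cells, differed by -0.11 and 0.06 (SE 0.36 for both, adjusted p = 0.820 and 0.890), and Stat5a, which carries the prolactin signal, by -0.76 and -0.61 (SE 0.34 for both, adjusted p = 0.0672 and 0.130). Stat5a was called with array weights (adjusted p = 0.0221 and 0.00758) and as the mean of all its probe sets (-1.71, adjusted p = 0.00752, and -1.75, adjusted p = 0.00551), in CBA/CaH without the arrays that stood apart (adjusted p = 0.0115) and in QSi5 without the pregnancy QSi5 array 4 (-0.89, adjusted p = 0.00767). Prlr was not analysed here. Some list calls also depended on the filter or another setting. With probe sets under a mean of 5 left out, the myoepithelial (adjusted p = 0.139), endothelial (adjusted p = 0.139), MHC (adjusted p = 0.180) and immediate early lists (adjusted p = 0.198) in CBA/CaH were not called, nor were the white adipocyte (adjusted p = 0.207), endothelial (adjusted p = 0.0963) and mitochondrial lists (adjusted p = 0.302) in QSi5. Equal array medians ended the MHC (adjusted p = 0.0611) and immediate early calls (adjusted p = 0.0536) in CBA/CaH and the white adipocyte call in QSi5 (adjusted p = 0.0519), and the mean of all probe sets that of the myoepithelial list in CBA/CaH (adjusted p = 0.121) and the mitochondrial list in QSi5 (adjusted p = 0.0877).

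**Figure D2:**
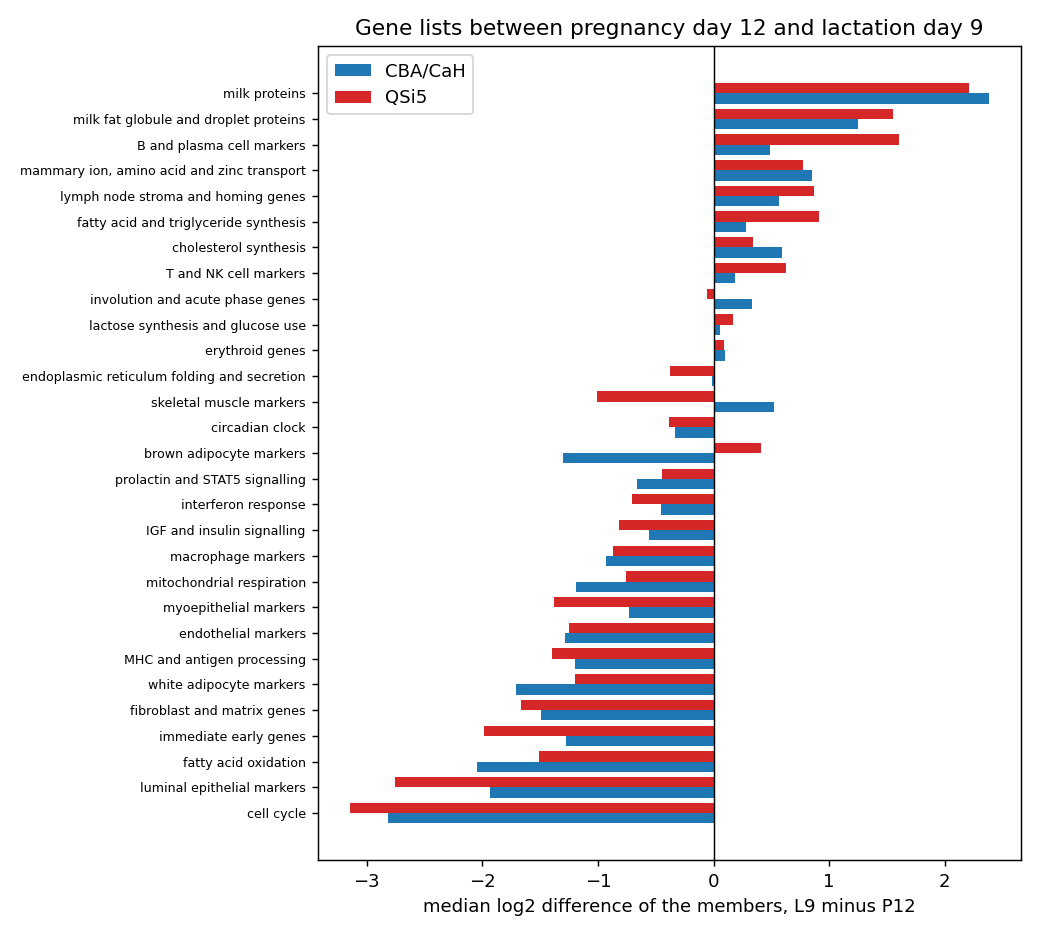
Median log2 difference of the measured members of each of the 29 gene lists, lactation day 9 minus pregnancy day 12, in CBA/CaH and QSi5. Bars start at 0, and the cell cycle list had the most negative bars.

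Across all probe sets, limma called 23849 between the stages in CBA/CaH (14546 higher and 9303 lower at lactation) and 26596 in QSi5 (16186 and 10410). These covered 12945 and 13815 genes. The median difference over all probe sets was 0.17 in CBA/CaH and 0.19 in QSi5, and the split depended on this shift. With array medians set equal it became 9095 higher and 11119 lower in CBA/CaH, and 9733 and 12778 in QSi5. Among probe sets with a mean level of at least 5, 5941 were higher and 8479 lower in CBA/CaH, and 6477 and 9343 in QSi5. Changes of at least 2-fold were called higher in 2023 and lower in 5939 probe sets in CBA/CaH, and in 3068 and 6777 in QSi5. The stage differences of both strains correlated across probe sets (r = 0.928, rho = 0.905), which are not independent replicates. In both strains 20650 probe sets were called in the same direction, against 7378 expected by chance, and 27 in opposite directions.

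The next question was which genes differed between the strains at each stage. On day 12 of pregnancy, major histocompatibility genes were among those that differed, with differences given as QSi5 minus CBA/CaH. H2-D1, a class I antigen-presenting molecule, was higher in QSi5 by 3.37 (SE 0.22, adjusted p = 2.17e-07, n = 5 and 5) and H2-K1, of the same class, by 2.84 (SE 0.27, adjusted p = 1.72e-05). H2-Eb1, a class II chain, was lower in QSi5 (-2.97, SE 0.22, adjusted p = 6.87e-07). Coro2a, an actin-binding protein, was higher by 3.64 (SE 0.33), Tnfsf13os, an antisense transcript, by 4.11 (SE 0.24) and Shisa2 by 3.04 (SE 0.38). Pdxdc1 (-4.68, SE 0.21), Ccdc122 (-3.67, SE 0.17) and Ceacam10 (-2.45, SE 0.34) were lower. Other probe sets of H2-D1 differed by -6.51 and -0.92 and another of Pdxdc1 by 2.40, each opposite to the value given, and the mean of all probe sets of Pdxdc1 was not called (-0.30, adjusted p = 0.688).

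Among 12 milk protein genes, 1 was called at this stage, Ltf, the iron-binding protein lactoferrin (1.45 higher in QSi5, SE 0.32, adjusted p = 0.0374, and 1 adjusted over the list alone). The Ltf call was lost without any 1 of the pregnancy CBA/CaH arrays 1, 3 and 5 or the pregnancy QSi5 arrays 1, 3 and 5 (adjusted p = 0.0869 to 0.114), without the arrays that stood apart (adjusted p = 0.841) and with only the compared groups in the fit (adjusted p = 0.0919). Wap (0.72, SE 0.51, adjusted p = 0.792) was not called, and Csn2 (-0.13, SE 0.13, adjusted p = 0.888) lay too close to the top of the range to test a difference. Muc1, a mucin of the luminal surface and the milk fat globule, was higher in QSi5 by 1.92 (SE 0.18, adjusted p = 1.54e-05). Slc34a2 was lower (-1.33, SE 0.26, adjusted p = 0.0181), a call lost without the pregnancy CBA/CaH array 2 or the pregnancy QSi5 array 2 or 3 (adjusted p = 0.0521 to 0.0566) and with only the compared groups in the fit (adjusted p = 0.0902).

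By list, camera called 8 of 29 at this stage. Luminal markers were higher in QSi5, with 2 of 12 members called, Prom1 (1.08, SE 0.19) and Krt7 (0.92, SE 0.18), and 3 adjusted over the list alone (adjusted p = 0.000613, with adjusted p = 0.640 with an estimated correlation). Neither member was called without the arrays that stood apart (adjusted p = 0.0743 and 0.412), Prom1 was not with only the compared groups in the fit (adjusted p = 0.0555) and Krt7 was not after quantile normalization (adjusted p = 0.085). Cell cycle genes were higher, with 1 of 29 called, Birc5 (0.80, SE 0.18, adjusted p = 0.0477), and 5 adjusted over the list alone (adjusted p = 0.00531, with adjusted p = 0.764 with an estimated correlation). The Birc5 call was lost without any 1 of 8 arrays (pregnancy CBA/CaH 2, 3, 4 and 5, pregnancy QSi5 1, 2, 3 and 5; adjusted p = 0.0512 to 0.127), without the arrays that stood apart (adjusted p = 0.179), after quantile normalization (adjusted p = 0.0856) and after cyclic loess (adjusted p = 0.0715). Fatty acid oxidation genes were lower, with 1 of 15 called, Ech1 (-1.34, SE 0.21), and 2 adjusted over the list alone (adjusted p = 1.48e-07, with adjusted p = 0.640 with an estimated correlation). Their median was 2.04 above the mean of all arrays on the pregnancy CBA/CaH array 5 and less on the other 4, and Ech1 was not called without the arrays that stood apart (adjusted p = 0.0601). Skeletal muscle (adjusted p = 7.19e-05) and immediate early genes (adjusted p = 0.00283) were higher as lists, and fatty acid synthesis (adjusted p = 0.0229), brown adipocyte (adjusted p = 0.0124) and mitochondrial respiration genes (adjusted p = 0.00663) lower, all with adjusted p = 0.764 with an estimated correlation. Without the arrays that stood apart, only the luminal and cell cycle lists of these 8 kept their call. The fatty acid oxidation (adjusted p = 0.0782), brown adipocyte (adjusted p = 0.433) and immediate early lists (adjusted p = 0.0635) lost it, and the skeletal muscle, fatty acid synthesis and mitochondrial lists turned direction and were not called (adjusted p = 0.137, 0.194 and 0.137).

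In all, limma called 492 probe sets at day 12 of pregnancy, 293 higher and 199 lower in QSi5, in 361 genes. Without the arrays that stood apart, which left 3 CBA/CaH and 2 QSi5 arrays, the count was 289. It was 894 without the pregnancy QSi5 array 4. Apart from the arrays numbered 4, CBA/CaH arrays had higher Gapdh 3' minus 5' values than QSi5 arrays, which limits these calls.

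On day 9 of lactation, Fhad1 (-5.56, SE 0.50, adjusted p = 2.90e-05, n = 3 and 3), Mt2, a metallothionein (-4.22, SE 0.57, adjusted p = 0.00188), and Saa3, an acute phase protein (-3.24, SE 0.48, adjusted p = 0.00423), were among the genes lowest in QSi5. Saa1 (-5.08, SE 0.84), Saa2 (-3.74, SE 0.74) and Orm2 (-3.39, SE 0.53) were also called. Their calls were lost without the lactation QSi5 array 2 or 3 for Saa1 (adjusted p = 0.0705 to 0.0764), the lactation CBA/CaH array 3 or any QSi5 array for Saa2 (adjusted p = 0.110 to 0.222) and the lactation QSi5 array 2 for Orm2 (adjusted p = 0.0535). None of Saa3, Saa1, Saa2 and Orm2 was called without the arrays that stood apart (adjusted p = 0.102, 0.097, 0.351 and 0.144). Their differences in that setting were -3.05, -4.90, -3.62 and -3.09. H2-D1 (2.75, SE 0.29) and H2-K1 (2.60, SE 0.35) were higher in QSi5 at this stage too, as was Ctse, an endosomal protease (2.70, SE 0.31). Slc16a1, a lactate carrier (-2.95, SE 0.32), Capg, an actin-capping protein (-2.61, SE 0.24), Pdxdc1 (-2.48, SE 0.27) and H2-Eb1 (-1.84, SE 0.28) were lower. H2-Q2 was higher by 2.40 (SE 0.48, adjusted p = 0.0462) and Golt1b lower (-2.04, SE 0.36, adjusted p = 0.0167), and both calls were lost without any 1 of the lactation CBA/CaH arrays or the QSi5 arrays 1 and 3 (adjusted p = 0.121 to 0.251 and 0.0639 to 0.120). In a fit of all 26 arrays Fhad1 (adjusted p = 0.0547), Saa3 (adjusted p = 0.128), Saa1 (adjusted p = 0.198), Saa2 (adjusted p = 0.370), Orm2 (adjusted p = 0.440), H2-K1 (adjusted p = 0.0936), Ctse (adjusted p = 0.313) and H2-Q2 (adjusted p = 0.427) were not called. With only the compared groups Saa2 (adjusted p = 0.217) and Orm2 (adjusted p = 0.0682) were not called, and with equal array medians Saa2 (adjusted p = 0.0542) and H2-Q2 (adjusted p = 0.0711). Averaged over its probe sets, Pdxdc1 was 0.10 and not called (adjusted p = 1), nor were H2-D1 (adjusted p = 0.109), Ctse (adjusted p = 0.265) and Golt1b (adjusted p = 0.101). Another H2-D1 probe set differed by -5.77 and another of Pdxdc1 by 2.19.

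Ppargc1a, a coactivator of mitochondrial genes, was higher in QSi5 by 1.82 (SE 0.29, adjusted p = 0.00675), a call lost without the lactation CBA/CaH array 3 (adjusted p = 0.0523) and as the mean of its probe sets (adjusted p = 0.393). Csn2 (-0.04, SE 0.17) and Wap (-0.01, SE 0.65) lay at the top of the range in both strains, so these values do not test a difference. Camera called 9 lists at lactation. B and plasma cell (adjusted p = 9.27e-05), T and NK cell (adjusted p = 0.000600), MHC (adjusted p = 0.000673), cell cycle (adjusted p = 0.000600) and fatty acid synthesis lists (adjusted p = 0.00116) were higher in QSi5, with adjusted p = 0.522 to 0.699 with an estimated correlation. No B and plasma cell marker passed limma's test over all probe sets (3 were higher and 1 lower adjusted over the list alone), and Ms4a1 differed by 1.30 (SE 0.71, adjusted p = 1). The median level of these markers was 0.789 higher in QSi5 than in CBA/CaH. Without the lactation QSi5 array 2 that difference was -0.151, while the median of the members' differences was 0.04. Their median against the mean of all arrays was 1.62 on that array, 0.43 and 0.30 on the other QSi5 arrays and at most 0.21 on the CBA/CaH arrays. The median of the MHC list was 0.74 above the mean of all arrays on that array and at -0.71 and -0.85 on the other QSi5 arrays. Involution and acute phase genes (1 of 16 called, 2 adjusted over the list alone; adjusted p = 1.57e-07), endoplasmic reticulum folding genes (3 adjusted over the list alone; adjusted p = 1.63e-05), myoepithelial markers (adjusted p = 0.0204) and circadian clock genes (adjusted p = 0.0412) were lower, with adjusted p = 0.522 to 0.831 with an estimated correlation. The median of the involution list was 1.23 on the lactation CBA/CaH array 1 and -0.25 and -0.35 on the other 2. That of the fatty acid synthesis list was -0.68 on this array and 0.08 and -0.06 on the other 2, against 0.24, 0.03 and 0.24 in QSi5. Both calls thus lean on the CBA/CaH array 1. Without the arrays that stood apart (at lactation the QSi5 array 2, but not the CBA/CaH array 1) only the involution, endoplasmic reticulum and fatty acid synthesis lists of these 9 kept their call. The others were the B and plasma cell (adjusted p = 0.169), T and NK cell (adjusted p = 0.505), MHC (adjusted p = 0.122), cell cycle (adjusted p = 0.107), myoepithelial (adjusted p = 0.561) and clock lists (adjusted p = 0.169). Creld2, a folding factor of the secretory pathway, differed by -0.99 (SE 0.29, adjusted p = 0.411), Scd1 by 0.89 (SE 0.39, adjusted p = 0.877) and Lpin1 by 1.08 (SE 0.40, adjusted p = 0.718).

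In all, limma called 130 probe sets at lactation, 65 higher and 65 lower in QSi5, in 96 genes. The count was 83 to 95 without any 1 array, 71 without x, s and a probe sets (those that can bind several transcripts) and 227 with array weights. Of the 492 called at pregnancy, 408 (82.9%) had the same sign at lactation. In 55 probe sets the call was made at both stages in the same direction, where fewer than 1 was expected by chance.

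**Figure D3:**
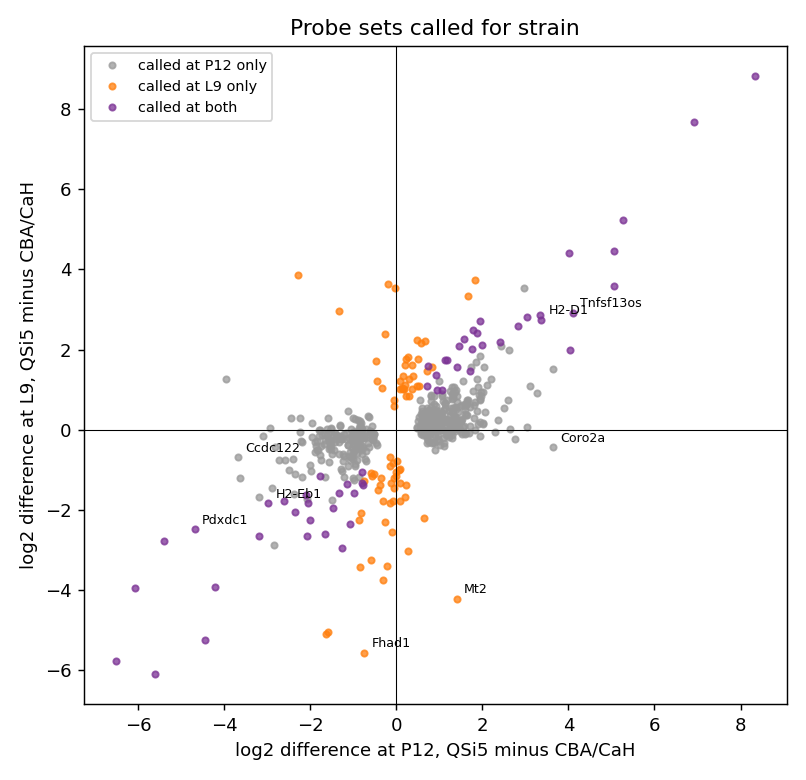
Strain difference (QSi5 minus CBA/CaH, log2) of each probe set called at 1 stage or at both, at day 12 of pregnancy (horizontal axis) and day 9 of lactation (vertical axis). Labelled points are named genes, and Mt2 and Fhad1 lay below 0 at lactation.

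Whether the strain difference itself changed between the stages was tested as an interaction. Mt2 (-5.63, SE 0.72, adjusted p = 0.00451) and Mt1, another metallothionein (-2.83, SE 0.41, adjusted p = 0.0109), were lower in QSi5 at lactation relative to pregnancy, as were Fhad1 (-4.82, SE 0.63) and Coro2a (-4.07, SE 0.54). Ccdc122 was 2.98 higher in that contrast (SE 0.29, adjusted p = 0.000453), Cspg5, a neural proteoglycan, 2.14 (SE 0.32) and Capn9, a protease, 1.58 (SE 0.24). The Cspg5 call was lost without the lactation QSi5 array 1 (adjusted p = 0.0568). Pdxdc1 (2.20, SE 0.34), Cyp7b1, a sterol hydroxylase (1.65, SE 0.28), and Hspa1b, a heat shock protein (-2.05, SE 0.34), were also called. Their calls did not hold with each array left out in turn, while the differences moved less. Without the lactation CBA/CaH array 3, for example, these were 2.01, 1.60 and -1.90. The Pdxdc1 call was lost without the lactation CBA/CaH array 3 or the lactation QSi5 array 1 or 3 (adjusted p = 0.0729 to 0.0767). That of Cyp7b1 was lost without any 1 of 11 arrays (pregnancy CBA/CaH 1, 3 and 5, pregnancy QSi5 1, 2 and 3, lactation CBA/CaH 1, 2 and 3, and lactation QSi5 1 and 3; adjusted p = 0.053 to 0.121). That of Hspa1b was lost without any 1 of 9 arrays (pregnancy CBA/CaH 1 and 3, pregnancy QSi5 1 and 2, lactation CBA/CaH 1, 2 and 3, and lactation QSi5 1 and 2; adjusted p = 0.0546 to 0.121). Without the arrays that stood apart, Mt2 (adjusted p = 0.184), Mt1 (adjusted p = 0.379), Fhad1 (adjusted p = 0.094), Capn9 (adjusted p = 0.162) and Hspa1b (adjusted p = 0.0872) were not called. Their differences in that setting were -4.73, -2.22, -3.91, 1.69 and -1.73. Fitted with all 26 arrays, the calls of Fhad1 (adjusted p = 0.380), Pdxdc1 (adjusted p = 0.339) and Cyp7b1 (adjusted p = 0.163) were lost. As the mean of their probe sets Mt1 (adjusted p = 0.0731), Pdxdc1 (adjusted p = 0.984), Cyp7b1 (adjusted p = 0.200) and Hspa1b (adjusted p = 0.552) were not called. Limma called 47 probe sets (24 higher and 23 lower) in 32 genes, a count that was 25 to 84 without any 1 array, 22 without x, s and a probe sets and 152 with array weights. Camera called 13 lists, among them fatty acid synthesis (adjusted p = 6.61e-05) and T and NK cells (adjusted p = 8.21e-05) as higher and luminal markers (adjusted p = 0.000267) as lower in QSi5 at lactation. With an estimated correlation these had an adjusted p = 0.489, and all 13 lay between adjusted p = 0.489 and 0.770 with an estimated correlation. Of the 13, 5 kept their call without the arrays that stood apart, T and NK cells and luminal markers among them, and fatty acid synthesis did not (adjusted p = 0.198).

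AIL mice at lactation were compared with each parental strain and with the mean of the parents. Against the mean of the parents, Net1 was higher by 2.82 (SE 0.15, adjusted p = 2.41e-10, n = 10 and 6) and Lum by 2.63 (SE 0.17, adjusted p = 1.76e-09). Itgb1, an integrin chain, was higher by 2.33 (SE 0.13) and Wls, which carries Wnt proteins, by 2.15 (SE 0.15), while a dim probe set of each was lower (-0.39 and -0.34). Malat1, a nuclear noncoding RNA (-1.51, SE 0.20), Serpina1c, a protease inhibitor (-1.54, SE 0.15), and Shh, a signalling protein (-1.35, SE 0.10), were lower, but a dimmer probe set of Malat1 was 0.64 higher. The AIL arrays differed from the parental arrays in a control as well. The 3' minus 5' value of the poly-A transcripts added to each sample was 0.387 (SD 0.069, n = 10) on the AIL arrays and 1.76 (SD 0.215, n = 6) on the parental lactation arrays, without overlap. When the 3' minus 5' value of Gapdh was a covariate, 746 probe sets were called for AIL against the mean of the parents. That value was 0.54 to 0.80 on the AIL arrays and at least 1.12 on the parental lactation arrays. The covariate is therefore confounded with AIL, and a call lost with it can come from lower precision. With it, the difference of Adipoq turned direction (-0.08, adjusted p = 0.963), as did that of Il2rb (0.03, adjusted p = 0.974). Of the other genes named against the mean of the parents, the covariate ended the calls of Wls, Malat1, Serpina1c, Col1a1, Col1a2, Cidec, Gpat4, Fasn, Pecam1, C1qb and Idh3a (adjusted p = 0.0504 to 0.486), but not those of Net1, Lum, Itgb1 and Shh.

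Matrix and fat genes were higher in AIL mice. Of 18 fibroblast and matrix genes, all 18 were called higher than the mean of the parents (18 adjusted over the list alone; adjusted p = 7.84e-09, with adjusted p = 0.291 with an estimated correlation), including Col1a1 (1.51, SE 0.17) and Col1a2 (1.61, SE 0.18), both collagen chains. A dim probe set of Col1a2 was lower (-0.25). Of 13 white adipocyte markers, 12 were higher (12 adjusted over the list alone; adjusted p = 5.39e-05, with adjusted p = 0.291 with an estimated correlation), such as Cidec (1.86, SE 0.24) and Adipoq (1.36, SE 0.23). The median of these markers, taken against the mean of all arrays, was -0.12 to 0.58 on the AIL arrays numbered 1 to 3. On AC4, AC5, AQ4 and AQ5 it was -0.67, -0.34, 0.04 and -0.59, and on the parental lactation arrays -1.26 to -0.53. Of 27 fatty acid and triglyceride synthesis genes, 19 were higher (20 adjusted over the list alone; adjusted p = 9.08e-06, with adjusted p = 0.291 with an estimated correlation), such as Gpat4, an acyltransferase (1.33, SE 0.12), and Fasn, the fatty acid synthase (0.66, SE 0.16, adjusted p = 0.00236). Endothelial markers (9 of 11 higher; 9 adjusted over the list alone), macrophage markers (10 of 16 higher, 1 lower; 10 and 1 adjusted over the list alone), mitochondrial respiration (12 of 18 higher, 1 lower; 12 and 1 adjusted over the list alone) and fatty acid oxidation genes (9 of 15 higher; 9 adjusted over the list alone) were called higher as lists, with adjusted p = 0.00426, 0.00321, 0.000114 and 0.000339. Their adjusted p with an estimated correlation was 0.451, 0.291, 0.331 and 0.291. The endothelial median, taken in the same way, was 0.18 to 0.36 on the AIL arrays numbered 1 to 3 but -0.53 to -0.58 on those numbered 4 and 5, and -0.65 to -0.84 on the parental lactation arrays. For fibroblast and matrix genes these were 0.12 to 0.35, -0.22 to -0.35 and -0.72 to -1.30. Examples are Pecam1, an endothelial adhesion molecule (1.26, SE 0.21), C1qb, a complement chain (1.58, SE 0.15), and Idh3a (1.77, SE 0.17), of which another probe set was lower (-0.79). T and NK cell markers were lower, with 9 of 14 called (9 adjusted over the list alone; adjusted p = 0.00659, with adjusted p = 0.451 with an estimated correlation), such as Il2rb, an interleukin receptor chain (-0.64, SE 0.13). With the arrays that stood apart left out, 5 of 14 were lower, with a median of -0.26 (adjusted p = 0.0448), and the median on the lactation QSi5 array 2 was 0.96, against 0.19 and 0.27 on the other QSi5 arrays. Of the milk protein genes 2 of 12 were higher (2 adjusted over the list alone; the list was not called, adjusted p = 0.305), and Csn2 (0.02, SE 0.06) and Wap (-0.05, SE 0.06) lay at the top of the range in AIL and parents, where a difference cannot be tested. In all, camera called 15 lists against the mean of the parents, 14 higher and 1 lower, with adjusted p = 0.291 to 0.451 with an estimated correlation. The myoepithelial and clock lists lost their call without the arrays that stood apart (adjusted p = 0.0835 for both). With probe sets under a mean of 5 left out 8 lists were called, and the macrophage (adjusted p = 0.0545) and endothelial lists (adjusted p = 0.0602) were not.

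Against each parent separately, AIL mice had Lum higher by 2.68 over CBA/CaH and 2.57 over QSi5 (SE 0.21 for both). Mt2 was lower than in CBA/CaH (-3.14, SE 0.44), and Car2, a carbonic anhydrase, was higher than in CBA/CaH by 2.64 (SE 0.24). H2-D1 lay between the parents, 1.42 above CBA/CaH (SE 0.27) and below QSi5 (-1.33, SE 0.27), but the mean of its probe sets turned the latter direction (0.17, adjusted p = 0.547), and other probe sets were 6.15 and 0.69 above QSi5. Dusp1, a phosphatase induced by stress, was 2.49 higher than in QSi5 (SE 0.31) and Ppargc1a lower (-1.57, SE 0.19). Fhad1 was 3.26 above QSi5 (SE 1.11, adjusted p = 0.0292), a call lost without any 1 of the lactation QSi5 arrays (adjusted p = 0.0669 to 0.114) without the arrays that stood apart (adjusted p = 0.139), with array weights (adjusted p = 0.0537) and with another variance model (adjusted p = 0.0783). With the Gapdh value as a covariate Mt2 (adjusted p = 0.439), Car2 (adjusted p = 0.0775), H2-D1 (adjusted p = 0.178 and 0.415), Dusp1 (adjusted p = 0.101) and Fhad1 (adjusted p = 0.480) were not called. These losses too can come from lower precision, as the covariate is confounded with AIL. Limma called 14425 probe sets against CBA/CaH (6611 higher and 7814 lower in AIL), 16220 against QSi5 (7085 and 9135) and 20528 against the mean of the parents (8550 and 11978). Without the lactation CBA/CaH array 3, 9481 were called against CBA/CaH. With array medians set equal the splits became 8104 and 4627, 9047 and 4944, and 10914 and 7065. The calls against both parents shared 10282 probe sets of the same direction, where 2625 were expected of independent calls, and 31 of opposite direction. These comparisons share the AIL arrays, which alone gave a correlation of 0.233 between their differences in simulated data without any difference, against 0.807 in the data. Comparisons without a shared array shared 7887 (1806 expected, 34 opposite) and 7790 (1822 expected, 39 opposite). These still set AIL arrays against parental arrays, which differed in the added poly-A controls. A difference between the sets of arrays could therefore give such an overlap by itself.

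The last comparisons set the AQ-coded AIL mice against the AC-coded ones. Ltf differed by 0.44 (SE 0.32), H2-K1 by 1.11 (SE 0.51), Srebf1 by -0.60 (SE 0.32), Fasn by -0.16 (SE 0.19) and Csn2, at the top of the range, by 0.02 (SE 0.07), each with adjusted p = 1. Limma called 0 of 45037 probe sets, while 1289 had an unadjusted p under 0.05, and the lowest adjusted p was 0.234. Camera called 7 lists, with cell cycle (adjusted p = 5.81e-05) and white adipocyte markers (adjusted p = 0.00199) higher in AQ and skeletal muscle (adjusted p = 1.26e-06) and fatty acid synthesis genes (adjusted p = 0.00319) lower. All 4 had adjusted p = 0.744 with an estimated correlation. The skeletal muscle markers were high on the array AIL AC1, and without it and the other arrays that stood apart the list turned direction (adjusted p = 0.0305). The AIL arrays formed 2 sets across both codes, numbers 1 to 3 and numbers 4 and 5. With these sets as a factor limma again called 0 probe sets, and 6 of the 7 lists kept their call, these 4 among them.

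Each AIL array was placed between the parental lactation arrays by the 492 probe sets called for strain at pregnancy (0% at CBA/CaH and 100% at QSi5). AIL mice lay at 57.9% (SD 8.23, n = 10) on average, between 41.5% and 67.6%. The AIL arrays also differed from the parental arrays in the added controls, and a difference between the sets of arrays can move this position. AC-coded mice lay at 58.1% (SD 7.39, n = 5) and AQ-coded mice at 57.7% (SD 9.89, n = 5), a difference of -0.332 percentage points (exact two-sided permutation test over 252 splits, p = 0.929, or p = 0.900 over the 120 splits within the 2 sets of AIL arrays). Of the 130 probe sets called for strain at lactation, 102 (78.5%) had an AIL mean between the parental means. These probe sets were chosen for a difference between the same parental arrays, which itself favours a mean between them. A share for other probe sets was not taken, so no conclusion is drawn from it.

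**Figure D4:**
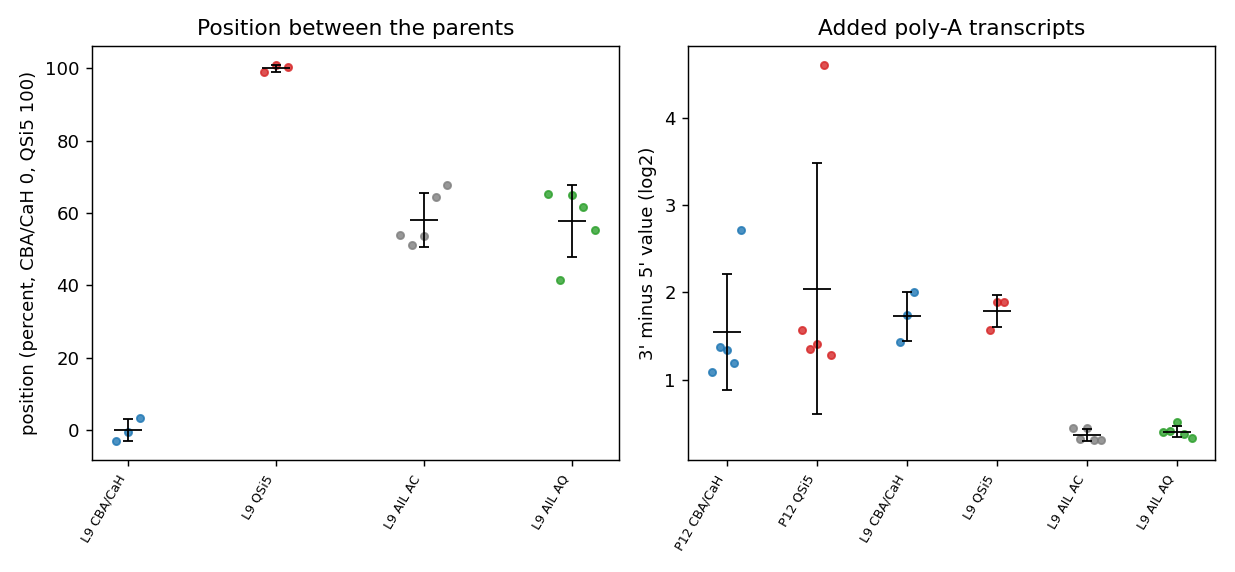
Left, position of each lactation array between the parental strains (percent, CBA/CaH at 0 and QSi5 at 100). Right, 3' minus 5' value of the added poly-A transcripts (log2) on each array of all groups. Points are arrays, bars are mean and SD, and the AIL arrays lay between 0.308 and 0.513 on the right.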

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

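The 3 tests of the AIL arrays against the parental lactation arrays were chosen only after the difference was seen, and so were the arrays that stood apart and the Gapdh covariate. The other tests and their bounds were written before the results they measure.

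The AIL arrays differed from the parental lactation arrays in 20528 probe sets against the mean of the parents. For a lower share of secretory epithelium in the AIL glands, milk fat genes met the bound set against it. Of these, 6 of 10 were higher and 0 lower with or without the arrays that stood apart. T and NK cell markers had a median of -0.362 (9 of 14 called lower), or -0.259 (5 of 14, short of the bound) without them. These values cannot decide it, because the AIL arrays also differed in the added controls and other values go with it. The fibroblast, white adipocyte, endothelial and macrophage lists were higher in AIL. Milk protein genes made up 2.91% of the linear signal on the AIL arrays, against 3.09% in CBA/CaH and 3.08% in QSi5 at lactation. Csn2 and Wap, large terms of that sum, lay at the top of the range, so this share does not test a difference. A signal range that depends on the level is argued against as the whole cause, since 16624 probe sets were called after cyclic loess. A difference in labelling stays open and may account for a part. The 3' minus 5' value of the added bacterial poly-A transcripts differed by -1.37 with no overlap (exact permutation test, p = 0.000125, the smallest that 8008 splits can give), but the slopes on that value over the 10 pregnancy arrays gave the called sign in 76.8% of probe sets, or 66.0% without the pregnancy QSi5 array 4, and a difference of the AIL genotype is confounded with the set of arrays and was not tested.

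Strain differences could come from sequence variants under single probes, from lymph node tissue in the sample, or from alleles of the strains. Among bright probe sets of the same genes, 69.64% (344 of 494, 95% interval 62.7% to 76.4%) had the direction of the called one at pregnancy, against 60.6% for genes not called, which lies between the bounds set for and against sequence variants and leaves them open. The B cell, T cell and lymph node lists shifted by 0.789, 0.458 and 0.546 towards QSi5 at lactation, but by -0.151, 0.199 and -0.067 without the lactation QSi5 array 2, although by the members' own differences the B cell list then stayed at 0.04 and its centred median higher on both other QSi5 arrays (0.43 and 0.30) than on any CBA/CaH array (at most 0.21). The bound set against lymph node tissue, a shift within the spread of a group, was wrong where 1 of 3 arrays makes much of both the shift and the spread (SD 1.63 for the B cell list), so that this cannot be told apart from a strain difference in those lists. The ratio of AIL to parental variance at lactation had a median of 1.678 for probe sets called for strain at pregnancy. For probe sets not called, matched on level, it was 0.794. The former was 2.115 times the latter (95% interval 1.81 to 2.49, drawn over probe sets, which are not independent). Segregation of parental alleles would give such a value, though a segregating sequence variant would give it too.

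White adipocyte markers fell between pregnancy and lactation. A lower share of adipocytes in the RNA may be the reason, since all 13 markers were lower in both strains, with a median of -1.46 (SD 0.676). Only 46.2% of them (6 of 13) were called lower in both strains, short of the bound set for this explanation. A lower expression per adipocyte was not tested and cannot be told apart from it by these arrays.

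Other splits of the arrays were counted for each comparison. For stage, 1 of 56 splits called as many probe sets as the real one in CBA/CaH (23849, highest other 4948) and 1 of 56 in QSi5 (26596, highest other 10034), so that chance can be excluded. For strain at pregnancy 2 of 100 splits were as large (492), which met the bound set against chance. However, the split that exchanged CBA/CaH array 4 and QSi5 array 4 called 4210, several times the real count. It sorted the 10 pregnancy arrays by their Gapdh 3' minus 5' value without overlap (0.89 to 1.74 against 2.00 to 6.50). The same value of Actb, another control transcript, was sorted too (0.96 to 1.84 against 2.22 to 5.62). The split that goes with this value thus called more probe sets than strain, and the cause was not tested. For strain at lactation the 10 splits are too few (130, highest other 1, 1 of 10 as large). For the interaction the splits cannot exclude chance (47, highest other 68, 2 of 100 splits). A split that mixes the strains moves the strain difference itself into the spread, which can lower its count. For AIL, the real split called the most against CBA/CaH (14425, highest other 12, 1 of 100) and QSi5 (16220, highest other 74, 1 of 100). The same held against the mean of the parents (20528, highest other 7713, 1 of 100). A split that mixes AIL and parental arrays moves their difference into the spread, which can lower its count. These splits show only that AIL and parental arrays differed. They cannot tell the line from the set of arrays, as the added poly-A controls differed too. For AQ against AC the real count was 0, which any split reaches (100 of 100, highest other 87), so that the splits test nothing there.

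A single array lay far from the rest of its group in 29 of 263 groups of values, where 1 in 20 groups (13.2) would do so by chance. Of these, 13 were on the pregnancy QSi5 array 4. Its Gapdh 3' minus 5' value was 6.50 and its poly-A value 4.61. On it, Rspo1 (9.91), Armcx4 (7.84), Kit (7.43), Elf5 (10.98), Stat5a (9.15), Idh3a (8.21), H2-D1 (11.71), Shisa2 (6.89), H2-K1 (11.96) and Slc16a1 (8.22) were the lowest of the group and Capg (6.84) the highest. The pregnancy CBA/CaH array 5 had the highest poly-A value (2.71), the highest Fasn (14.04), Elovl5 (11.58) and Acadl (11.99) and extreme Cp (10.3) and Cspg5 (7.34). Cidec was 5.71 on the pregnancy CBA/CaH array 2. Among AIL arrays, AC1 stood out for the skeletal muscle markers (3.36) and Dusp1 (8.88), and AC3 for Idh3a (10.49) and Itgb1 (9.31). AQ4 stood out for Ccdc59 (5.65) and AQ5 for H2-D1 (9.12), H2-K1 (9.12) and Serpina1c (5.64). AQ3 was flagged for Csn2 (14.83) only against a narrow range at the top of the table, with 14.85 to 14.86 on the other AQ arrays.

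The strain difference changed between the stages, by the interaction test, for Coro2a (-4.07), Fhad1 (-4.82), Mt2 (-5.63), Mt1 (-2.83), Hspa1b (-2.05), Pdxdc1 (2.20), Ccdc122 (2.98), Cspg5 (2.14), Cyp7b1 (1.65) and Capn9 (1.58). Of these, Fhad1, Mt2, Mt1, Hspa1b and Capn9 were not called without the arrays that stood apart (adjusted p = 0.0872 to 0.379). Their differences in that setting were -3.91, -4.73, -2.22, -1.73 and 1.69. Outside the tested probe sets, the 5' value of the added poly-A transcripts, a term of the 3' minus 5' value above, was 9.05 on the AIL arrays (SD 0.46, n = 10) and 6.4 on the parental lactation arrays (SD 0.42, n = 6).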

How the results depend on the processing

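The arrays that stood apart, the Gapdh covariate, cyclic loess and the 2 sets of AIL arrays were chosen only after results were seen. Of the values of main results under other settings, 232 stayed the same, which for a count means within 1.5 times, whatever its split by direction. Of the rest, 35 were lower, 11 higher and 1 moved off 0. For named genes 4423 values stayed the same in call, 219 lost the call, 21 gained it and 4 turned direction. For called lists 468 values kept the call, 74 lost it and 5 turned direction. These list values leave out the estimated correlation, with which no list was called. The filter on a mean of at least 5 tested fewer probe sets and called 14300 for stage in CBA/CaH, 15714 in QSi5, 13197 for AIL against the mean of the parents, and 10 lists for AIL against QSi5 and 8 against the mean of the parents. Strain at pregnancy gave 306 with only the compared groups, 852 with all 26 arrays, 1579 with array weights, 319 without x, s and a probe sets, 289 without the arrays that stood apart (218 shared) and 928 with the covariate. Strain at lactation gave 218 when quantile normalized again, 227 with array weights, 71 without x, s and a probe sets and 216 with the covariate. The interaction gave 80 with all arrays, 152 with array weights, 22 without x, s and a probe sets and 84 with the covariate. The covariate left 557 (AIL against CBA/CaH), 837 (QSi5) and 746 (mean of the parents), and it is confounded with AIL. Leaving out 1 replicate gave 372 to 894 for strain at pregnancy (894 without P12 QSi5 replicate 4), 83 to 95 at lactation, 25 to 84 for the interaction (84 without P12 QSi5 replicate 4) and 9481 to 14328 for AIL against CBA/CaH (9481 without L9 CBA replicate 3), and 0 to 3 for AQ against AC (3 without AIL AQ replicate 4). Replicate numbers were not taken as pairs, as no pair of groups had all residual correlations of equal numbers over 0.1, although 4 of 5 were so for AC and AQ arrays (0.007 to 0.316, mean 0.175, against -0.044 for other numbers). The 2 sets of AIL arrays as a factor left 0 probe sets and 6 lists for AQ against AC. With the replicate block, limma called 21833, 24655, 435, 99, 32, 12744, 14014 and 17772 probe sets, and 0 for AQ against AC, and 6 list calls were not made, among them milk fat globule (adjusted p = 0.0511), white adipocyte and mitochondrial (adjusted p = 0.057 for both) for stage in QSi5. With an estimated correlation camera called 0 lists in every comparison. Without the arrays that stood apart, 5 lists were called for strain at pregnancy, 4 at lactation and 7 for the interaction, and for AQ against AC the mean of all probe sets gave 4. Directions turned for Pdxdc1 at lactation (0.0985) and H2-D1 in AIL against QSi5 (0.169) with the mean of all probe sets, for Adipoq (-0.0752) and Il2rb (0.0338) with the covariate, and without the arrays that stood apart for the fatty acid synthesis (adjusted p = 0.194), skeletal muscle (adjusted p = 0.137) and mitochondrial lists (adjusted p = 0.137) at pregnancy and the skeletal muscle list in the interaction (adjusted p = 0.805) and in AQ against AC (adjusted p = 0.0305). The AQ minus AC position was not past the threshold under any setting tried, from -2.22 to 8.67, the last as a median over probe sets (exact permutation test, p = 0.222). Except for the filters, which test fewer probe sets, the cause was not tested. Dim probe sets near background limit what small differences can show.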

Other observations

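The AIL arrays formed 2 sets by replicate number across both codes. Residual correlations between AC and AQ arrays averaged 0.115 within numbers 1 to 3, 0.239 within numbers 4 and 5, and -0.166 between these sets. The labels give no batch for them.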
